A study of Mus musculus with 7 samples.

How the data were processed

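The series holds RNA sequencing of SMB21 cells, a mouse medulloblastoma line from a Ptch1-mutant background that was grown as neurospheres. Ptch1 encodes the receptor that restrains the Hedgehog pathway, so the pathway is active in such tumours without ligand. Cells were infected with a lentiviral vector carrying Cas9 and a guide against GFP (control), Ofd1 or Kif3a, and RNA was collected 2 weeks later. Ofd1 is a centriole and basal body protein and Kif3a is a motor subunit of kinesin-2, and both are needed for primary cilia. The guide sequences, and whether clones or pools were sequenced, are not given in the sources used here, so the edited sites are not located. Stranded poly-A libraries were read as single-end reads of 75 bases in 1 sequencer run. The labels call the replicates biological. There were 2 GFP control libraries, 3 Ofd1 CRISPR libraries and 2 Kif3a CRISPR libraries, 7 in all; the series text counts 3 GFP replicates, of which 2 were analysed here.

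The deposited table holds raw counts, as whole numbers of reads per gene symbol and library, without normalization. STAR, DESeq2 and the build mm9 are named per the submitters' processing notes, with no version and no role. The read counter, the gene annotation, the strand setting and any filter are not given in the sources used here. Reads that map to several places and gene models that differ from mm9 can therefore move single genes by an unknown amount. Eno1, which has near-identical copies, carries almost no counts, and whether other such genes do was not tested. A reference for GRCm38 served only for gene names and synonyms, and its GENCODE M21 transcripts for GC content and length; no coordinates were taken from it. Library totals ran from 17961767 to 23022701 counts. Reads carry no molecular identifiers, so limits drawn from counts cover counting error only.

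Of 24047 genes in the table, 6795 had no count in any library, and 12875 passed edgeR's filterByExpr on the groups and were tested. These held 99.96% of all counts. Library totals were scaled with TMM factors. One edgeR quasi-likelihood model with a mean per group was fitted to all 7 libraries, which leaves 4 residual degrees of freedom, and each contrast was tested with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Every adjusted p printed for a gene is from this model unless another tool is named. The common biological coefficient of variation was 7.43%. Log2 fold changes carry a standard error (SE) derived from the F statistic, and levels are TMM-scaled CPM, the counts of a gene scaled to a common library total, with the standard deviation (SD) over libraries. A count of 3 in a library, taken as the largest expected count that an observed 0 leaves possible, corresponds to 0.130 to 0.167 CPM. The comparisons were Ofd1 CRISPR against GFP control, Kif3a CRISPR against GFP control and Ofd1 CRISPR against Kif3a CRISPR. The groups, the model, the threshold, the gene lists, the rule for named genes and the alternatives were set before the data were examined.

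The named genes were chosen by rule. Ofd1, Kif3a, Gli1, Gli2, Ptch1, Hhip, Smo, Sufu, Mycn, Ccnd1 and Atoh1 are given in the text. To these were added, for each comparison with GFP, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 2 CPM whose mutant libraries all lie on one side of all GFP libraries, and up to 3 called members per list with the smallest adjusted p. For Ofd1 against Kif3a the 5 largest changes each way were taken. For genes changed the same way in both mutants, the rule took the 10 with the largest smaller-of-both change each way. From each list the text gives examples. A clone identifier among the rises (1 gene) is left out. List members named outside the rule were chosen after their values were seen.

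The 24 gene lists were Hedgehog target genes, Hedgehog pathway components, kinesin-2 and intraflagellar transport, basal body, transition zone and BBSome, G1/S cell cycle, G2/M cell cycle, p53 target genes, granule neuron progenitor identity, granule neuron differentiation, neural stem cell and astrocyte markers, oligodendrocyte lineage markers, microglia and macrophage markers, endothelial markers, fibroblast and mesenchymal markers, motile cilia and ependymal markers, interferon response, ERK/MAPK feedback and early response, Wnt target genes, Notch pathway, BMP/TGF-beta targets, cholesterol biosynthesis, hypoxia and glycolysis, integrated stress and unfolded protein response, and RNA quality signs. Lists overlap in places: Mycn and Atoh1 stand in the Hedgehog target and granule progenitor lists, and Sesn2 in the p53 and stress lists. Members were counted as higher, lower or not passing over all tested genes, and again with p adjusted over the list alone. The 23 lists with at least 5 tested members were tested with limma's camera (preset inter-gene correlation 0.01, two-sided), adjusted over the 23 lists of a comparison. Camera was repeated with an estimated correlation, which also rests its test on the 4 residual degrees of freedom. Fry served as a self-contained test. The genes Hmgcs1, Disp1, Rn18s and Rn7sk were not analysed here.

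Both comparisons with GFP use the same 2 control libraries. Overlap and correlation between them were therefore set beside the overlap of independent lists and beside 20 simulations of unchanged groups that share the controls, with counts drawn at the fitted means and dispersions. Each part of a split control group would hold 1 library, so the controls were not split. Alternatives were DESeq2, limma-voom, RLE factors, library totals alone, no filter and a filter of at least 1 CPM in 2 libraries. DESeq2 was run on all genes with a count, without edgeR's filter. Further alternatives were only the 2 groups compared, a block for the replicate number, both other list tests, and leaving out each library in turn. Where leaving out a library left a group with 1 library, the spread was pooled from the other groups and the lone library was assumed to vary like them. The model was tested on simulated data with planted changes: of 100 genes per size, 87, 85 and 87 of the genes changed 2-fold and 83, 59 and 75 of those changed 1.5-fold were recovered in the 3 comparisons, and 10, 11 and 12 unchanged genes were called. Of 200 genes changed in both simulated mutants, 173 were recovered in both, with 2 false shared calls. Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with matplotlib 3.10.9.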

Results

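RNA from 7 cultures of SMB21 medulloblastoma cells was compared: 2 GFP control, 3 Ofd1 CRISPR and 2 Kif3a CRISPR libraries. The GFP control libraries held 20690243 and 20302206 counts, the Ofd1 CRISPR libraries 20014172, 17961767 and 19324637, and the Kif3a CRISPR libraries 23022701 and 18469525. The 10 most abundant genes took 2.38% to 2.86% of each library. On the first principal component, which held 54.1% of the variance, the GFP control libraries lay at -34.9 and -29.4 and the Ofd1 and Kif3a CRISPR libraries, called mutants for short although editing was not checked here, between 1.10 and 24.8. Within the mutants the libraries did not separate fully by guide: Ofd1 CRISPR replicate 2 differed less from Kif3a CRISPR replicate 2 (chi-square per degree of freedom 5.50) than from either other Ofd1 CRISPR library (9.19 and 7.34). The GFP control libraries differed from each other by 3.61 on this scale.

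The targeted genes were looked at first in each library. Kif3a stood at 104 CPM in both GFP control libraries, at 90.6, 93.1 and 97.4 CPM in the Ofd1 CRISPR libraries, and at 73.9 and 60.5 CPM in the Kif3a CRISPR libraries. It fell in Kif3a CRISPR by 0.63 on the log2 scale (SE 0.0929, adjusted p = 0.000854, lower in 2 of 2 libraries). Ofd1 stood at 22.6 and 23.2 CPM in GFP control, at 21.0, 20.03 and 22.0 CPM in Ofd1 CRISPR, and at 31.7 and 29.0 CPM in Kif3a CRISPR. Its log2 fold change in Ofd1 CRISPR was -0.12 (SE 0.0910, adjusted p = 0.398), so a lower Ofd1 transcript level was not detected in cells that carried its guide. In Kif3a CRISPR Ofd1 rose by 0.41 (SE 0.0975, adjusted p = 0.0126), a call that was lost without GFP control replicate 1 (adjusted p = 0.103), GFP control replicate 2 (0.0639) or Kif3a CRISPR replicate 1 (0.114). Small insertions and deletions made by Cas9 need not lower a transcript, and protein was not analysed here.

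The comparison of Ofd1 CRISPR with GFP control asks what changed in cells of a Ptch1-mutant line that carried a guide against this basal body gene. Among 12 tested Hedgehog target genes 6 fell, 1 rose and 5 did not pass, and camera's call on the list was lost with an estimated correlation (adjusted p = 0.212). Hhip, which encodes a Hedgehog-binding antagonist induced by the pathway, went from 135 ± 14.4 CPM (SD, n = 2) to 48.7 ± 18.5 CPM (SD, n = 3), a fall by 1.47 on the log2 scale (SE 0.239, edgeR adjusted p = 0.0023). Ptch1 fell by 0.91 (SE 0.152, adjusted p = 0.00265) and Ccnd1, which encodes cyclin D1, by 0.56 (SE 0.113, adjusted p = 0.00775). These 3 calls held without any 1 of the 7 libraries. Gli1, the transcription factor most used as a readout of the pathway, fell by 0.84 (SE 0.220, adjusted p = 0.0257), from 452 ± 35.2 CPM (SD, n = 2) to 253 ± 79.9 CPM (SD, n = 3). The Gli1 call was lost without GFP control replicate 1 (adjusted p = 0.0720) or GFP control replicate 2 (0.128).

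When adjusted over the list alone, 8 of the Hedgehog targets fell and 2 rose, and the median log2 fold change was -0.29. Camera with the preset correlation placed the list below other genes (adjusted p = 0.0024; adjusted p = 0.212 with an estimated correlation), and fry gave an adjusted p of 0.0293. Without GFP control replicate 1, and likewise without GFP control replicate 2, 3 members fell. Mycn fell by 0.30 (SE 0.0814, adjusted p = 0.0281), and lost its call without GFP control replicate 1 (0.238) or 2 (0.0996), Ofd1 CRISPR replicate 2 (0.0910), or Kif3a CRISPR replicate 1 (0.0506) or 2 (0.0503). The member that rose was Atoh1, a transcription factor of granule neuron progenitors, by 0.53 (SE 0.0923, adjusted p = 0.00322). Among 18 pathway components 3 fell, 1 rose and 14 did not pass (5 and 2 over the list alone, median -0.07, camera adjusted p = 0.582). The number that fell was 0 without GFP control replicate 1, 1 without GFP control replicate 2 and 5 without Ofd1 CRISPR replicate 3, by edgeR. Gli2 fell by 0.36 (adjusted p = 0.0167; 0.0726 and 0.142 without GFP control replicate 1 or 2) and Gas1, a Hedgehog co-receptor, by 0.48 (0.0138; 0.109 without GFP control replicate 1). Sufu, which restrains Gli proteins, fell by 0.28 (adjusted p = 0.0309), and lost its call without GFP control replicate 1 (0.160) or 2 (0.184), Ofd1 CRISPR replicate 1 (0.0612), or Kif3a CRISPR replicate 1 (0.0587) or 2 (0.0584). Smo, the signal transducer under Ptch1, had a log2 fold change of 0.13 (adjusted p = 0.243).

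**Figure D1:**
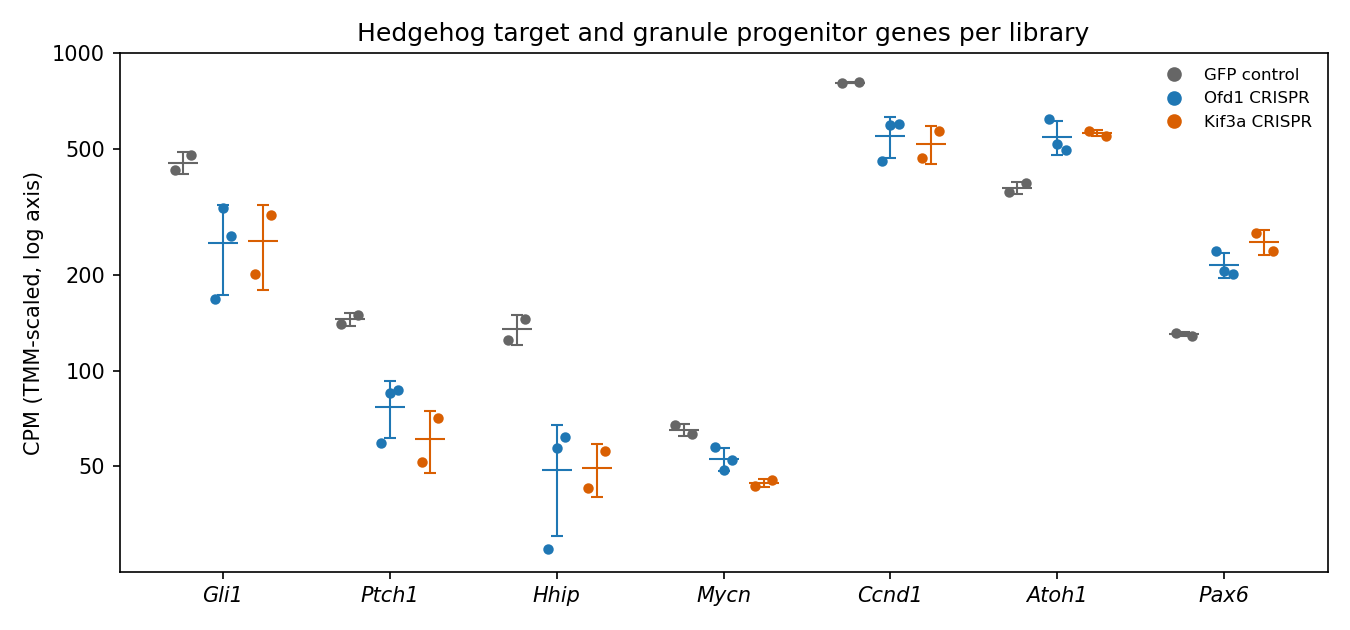
Levels of 7 genes in each of the 7 libraries, in TMM-scaled CPM on a log axis; points are libraries, horizontal lines group means and error bars the SD. Hhip averaged 135 CPM in GFP control, 48.7 in Ofd1 CRISPR and 49.4 in Kif3a CRISPR, while Atoh1 averaged 376, 544 and 558.

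Genes of the granule neuron lineage were higher in Ofd1 CRISPR. Of 17 progenitor identity genes 7 rose, 1 fell and 9 did not pass (9 and 1 over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 4.4e-05, fry 0.0293; adjusted p = 0.312 with an estimated correlation). Pax6 rose by 0.73 (SE 0.0868, adjusted p = 0.000458), from 130 ± 1.86 CPM (SD, n = 2) to 215 ± 19.5 CPM (SD, n = 3), Zic4 by 0.59 (SE 0.0883) and Meis1 by 0.46 (SE 0.0683); the member that fell was Mycn. Of 24 differentiation genes 12 rose, 3 fell and 9 did not pass (13 and 4 over the list alone), with a median of 0.35 (camera adjusted p = 5.4e-05, fry 0.0293; adjusted p = 0.208 with an estimated correlation). Gap43, a growth cone protein, rose by 1.23 (SE 0.116, adjusted p = 0.000208) and Dcx, a microtubule protein of migrating neurons, by 0.88 (SE 0.118, adjusted p = 0.000822). The adhesion molecule Ncam1 fell by 0.74 (SE 0.0950, adjusted p = 0.00075). Without GFP control replicate 1, and likewise without GFP control replicate 2, 5 progenitor genes and 6 differentiation genes rose, and 1 differentiation gene fell. The count of differentiation genes that rose was 7 without Ofd1 CRISPR replicate 1 and 8 without Ofd1 CRISPR replicate 2, Kif3a CRISPR replicate 1 or Kif3a CRISPR replicate 2. Of 17 neural stem cell and astrocyte markers 3 rose and 2 fell (3 and 2 over the list alone, camera adjusted p = 0.796). The stem cell factors Sox2 and Sox9 fell by 0.67 (SE 0.0762) and 0.65 (SE 0.0911), and Vim rose by 0.39 (adjusted p = 0.0082; 0.110 without GFP control replicate 2). Of this list 1 gene rose without GFP control replicate 1 and 0 rose by edgeR without GFP control replicate 2. Its mean was 0.05 while the median, -0.04, and the test pointed down.

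By number of members, the widest falls among the lists in Ofd1 CRISPR were in hypoxia and glycolysis and in the integrated stress response. Of 22 hypoxia and glycolysis genes 20 fell, 0 rose and 2 did not pass (21 and 0 over the list alone), with a median of -0.64 (camera adjusted p = 6.5e-22, fry 0.0293; adjusted p = 0.208 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell by 0.90 (SE 0.0940, adjusted p = 0.000276), the collagen prolyl hydroxylase P4ha1 by 0.65 (SE 0.0749, adjusted p = 0.000378) and the glucose transporter Slc2a3 by 0.55 (SE 0.0636, adjusted p = 0.0004). Of 22 stress and unfolded protein response genes 16 fell, 0 rose and 6 did not pass (17 and 1 over the list alone), with a median of -0.69 (camera adjusted p = 6.5e-18, fry 0.0250; adjusted p = 0.208 with an estimated correlation). Atf5, a transcription factor translated under stress, fell by 2.65 (SE 0.257, adjusted p = 0.00022), lower in 3 of 3 libraries. The pseudokinase Trib3 fell by 2.56 (SE 0.301) and the leucine sensor Sesn2 by 1.41 (SE 0.129), from 62.6 ± 13.1 CPM (SD, n = 2) to 23.6 ± 2.77 CPM (SD, n = 3). The endoplasmic reticulum chaperones Hspa5, Calr and Pdia4 had log2 fold changes of 0.06, -0.05 and -0.08 and did not pass. Without GFP control replicate 1, which carried myeloid transcripts, 14 hypoxia genes and 13 stress genes fell.

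Of 20 p53 target genes 8 fell, 0 rose and 12 did not pass (8 and 1 over the list alone), with a median of -0.23 (camera adjusted p = 4.4e-05, fry 0.00655; adjusted p = 0.208 with an estimated correlation). Gdf15, a secreted stress cytokine, fell by 3.01 (SE 0.435, adjusted p = 0.00123) and the cell cycle inhibitor Cdkn1a by 1.45 (SE 0.228, adjusted p = 0.00197). Mdm2 and Ccng1, which p53 induces in many cell types, had log2 fold changes of -0.02 and -0.06 and did not pass, and Sesn2 is also in the stress list. The p53 targets that fell numbered 5 without GFP control replicate 1 and 5 without GFP control replicate 2. Of 24 G1/S genes 6 fell and 18 did not pass (9 over the list alone, median -0.19, camera adjusted p = 0.000235). The list did not pass by fry (adjusted p = 0.168) or by camera with an estimated correlation (0.685). Ccne2, which encodes cyclin E2, fell by 0.67 (adjusted p = 0.00685; 0.0566 without GFP control replicate 1) and Cdt1, a replication licensing factor, by 0.41 (adjusted p = 0.00909; 0.0674 and 0.0625 without GFP control replicate 1 or 2). The count of 6 was 0 without GFP control replicate 1 by edgeR, 1 without GFP control replicate 2, 3 without Ofd1 CRISPR replicate 1, 4 without Ofd1 CRISPR replicate 2, 10 without Ofd1 CRISPR replicate 3 and 4 without Kif3a CRISPR replicate 1. Of 23 G2/M genes 1 rose and 1 fell (0 and 0 over the list alone, median 0.00, camera adjusted p = 0.657); the sign of this median flipped with RLE factors (-0.00390). No G2/M gene was called by edgeR without GFP control replicate 1 or 2 or without Ofd1 CRISPR replicate 1 or 2, none fell without Kif3a CRISPR replicate 1 or 2, and 6 fell without Ofd1 CRISPR replicate 3.

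Other lists in Ofd1 CRISPR moved in few members. Of 18 ERK/MAPK feedback genes 6 fell (8 over the list alone, median -0.24, camera adjusted p = 0.00227; adjusted p = 0.312 with an estimated correlation), among them the phosphatase Dusp4 by 1.17 (SE 0.211) and the Ets factor Etv5 by 0.63 (SE 0.129). That count was 2 without GFP control replicate 1 and 3 without GFP control replicate 2. Of 12 Wnt targets 2 fell (3 lower and 1 higher over the list alone, camera adjusted p = 0.139, fry 0.0293), with the Wnt inhibitor Wif1 down (-1.43, SE 0.192). That count depended on GFP control replicate 2. Of 14 Notch pathway genes 3 rose and 2 fell (4 and 6 over the list alone, camera adjusted p = 0.991, mean 0.04 against a median of -0.09); the effector Hey1 rose by 1.63 (SE 0.185) and Notch3 fell by 0.63 (SE 0.113). Of the Notch genes 1 rose and 1 fell without GFP control replicate 1, and likewise without GFP control replicate 2. Of 11 BMP/TGF-beta targets 1 fell (1 over the list alone, camera adjusted p = 0.991), of 22 cholesterol genes 3 rose (3 over the list alone, 0.139), and of 23 interferon response genes 3 fell (3 lower and 1 higher over the list alone, 0.646). Without GFP control replicate 2 no BMP/TGF-beta target fell and no cholesterol gene rose by edgeR, and 1 interferon gene fell; 1 also fell without Ofd1 CRISPR replicate 1 or 2. The cholesterol list passed camera without GFP control replicate 1 (adjusted p = 0.0499) or Ofd1 CRISPR replicate 1 (0.00307).

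Among cilium lists in Ofd1 CRISPR, 3 of 29 kinesin-2 and intraflagellar transport genes rose (3 over the list alone, camera adjusted p = 0.274) and 1 of 35 basal body, transition zone and BBSome genes rose (0 over the list alone, 0.541). None of these 4 cilium calls was kept without GFP control replicate 1 or without GFP control replicate 2 (0 genes by edgeR each). Without Ofd1 CRISPR replicate 1 or 2, 1 kinesin-2 and intraflagellar transport gene rose, and 4 basal body, transition zone and BBSome genes rose without Ofd1 CRISPR replicate 3 but 0 without any other library. Of 8 motile cilia markers 2 rose (3 higher and 1 lower over the list alone, 0.362), with Foxj1, the transcription factor of motile ciliogenesis, up by 1.45 (SE 0.251); 1 rose without GFP control replicate 1 and 1 without GFP control replicate 2. Among markers of other cell types, 1 of 5 oligodendrocyte (1 over the list alone, camera adjusted p = 0.308) and 3 of 10 fibroblast genes fell (3 over the list alone, 0.139). By fry both lists were lower (adjusted p = 0.0250 and 0.0293). Of 5 endothelial genes 1 fell (3 lower and 1 higher over the list alone, camera adjusted p = 0.0475, or 0.312 with an estimated correlation). No oligodendrocyte gene fell by edgeR without GFP control replicate 1, 1 fibroblast gene fell without GFP control replicate 1 or 2, and 2 endothelial genes fell without GFP control replicate 2 or Ofd1 CRISPR replicate 2 or 3. The endothelial call was lost without Ofd1 CRISPR replicate 1 (0.0599) or 2 (0.0656), or Kif3a CRISPR replicate 1 (0.0513) or 2 (0.0524). Of 8 RNA quality signs 1 fell (1 over the list alone, 0.991, median 0.07 against a test that pointed down), the nuclear RNA Neat1 (-0.37, adjusted p = 0.0259), a call lost without GFP control replicate 2 (0.313), Ofd1 CRISPR replicate 1 (0.061) or Ofd1 CRISPR replicate 2 (0.0515).

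In all, 1915 of 12875 tested genes changed in Ofd1 CRISPR, 874 higher and 1041 lower, of which 162 and 145 by more than 2-fold. With a block for the replicate number 3496 genes changed. Scaled by library totals alone, 2006 genes changed and 57.5% of them were higher, against 45.6% with TMM factors. Among genes with a mean of at least 2 CPM whose mutant libraries all lay on one side of the GFP control libraries, the largest rises were in Igfbp5, an insulin-like growth factor binding protein (3.36, SE 0.312), from 58.4 ± 1.30 CPM (SD, n = 2) to 600.1 ± 270.5 CPM (SD, n = 3), and in Grik3 (3.19), Cmya5 (3.09), Kcna1 (2.77), Cemip (2.67), Prph (2.66), Casz1 (2.60), Mroh2a (2.60) and Tspan4 (2.32). By the same criteria the largest falls were in Trim66 (-3.32, SE 0.281), Mef2b (-2.75), Atf5, Trib3, Chac1 (-2.49), Nupr1 (-2.45), Aldh1l2 (-2.43), Cabp1 (-2.18), Calb2 (-2.07) and the early response receptor Nr4a1 (-2.003, SE 0.136). Calls were lost without GFP control replicate 1 for Cmya5 (adjusted p = 0.0716), Kcna1 (0.0515) and Casz1 (0.0772), and without GFP control replicate 2 for Kcna1 (0.0844), Casz1 (0.0537) and Chac1 (0.0511). The total was 664 genes without GFP control replicate 1 and 816 without GFP control replicate 2.

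The comparison of Kif3a CRISPR with GFP control asks the same of a subunit of the ciliary motor. Of the 12 tested Hedgehog targets 6 fell, 1 rose and 5 did not pass (7 and 1 over the list alone). Their median was -0.59 (camera adjusted p = 0.0125, fry 0.0280, and camera adjusted p = 0.197 with an estimated correlation). The mean, -0.44, lay near the mean of -0.40 in Ofd1 CRISPR, where the median was -0.29. Ptch1 fell by 1.25 (SE 0.172, edgeR adjusted p = 0.000559), from 145 ± 7.15 CPM (SD, n = 2) to 61.1 ± 13.6 CPM (SD, n = 2), and Mycn by 0.56 (SE 0.0904, adjusted p = 0.00144); both calls held without any 1 library. Hhip fell by 1.45 (SE 0.269, adjusted p = 0.00315) and Ccnd1 by 0.64 (SE 0.126, adjusted p = 0.0047), and both were lost without Kif3a CRISPR replicate 1 (0.0964 and 0.103). Gli1 fell by 0.82 (SE 0.246, adjusted p = 0.0349) and lost its call without GFP control replicate 1 (0.0783), GFP control replicate 2 (0.127) or Kif3a CRISPR replicate 1 (0.321). The number of targets that fell was 4 without GFP control replicate 2 and 2 without Kif3a CRISPR replicate 1. Atoh1 rose by 0.57 (SE 0.0999, adjusted p = 0.00232). Among 18 pathway components 3 fell, 1 rose and 14 did not pass (3 and 1 over the list alone, median -0.04, camera adjusted p = 0.540). Of these 0 were called by edgeR without Kif3a CRISPR replicate 1. Gli2 fell by 0.47 (adjusted p = 0.00495; 0.0942 without Kif3a CRISPR replicate 1), and Sufu by 0.38 (0.00976), a call lost without GFP control replicate 1 (0.0603) or 2 (0.0628) or Kif3a CRISPR replicate 1 (0.0838) or 2 (0.0650). Smo had a log2 fold change of 0.11 (adjusted p = 0.327).

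Granule lineage genes were higher in Kif3a CRISPR. Of 17 progenitor identity genes 8 rose, 1 fell and 8 did not pass (9 and 1 over the list alone), with a median of 0.21 (camera adjusted p = 0.000202, fry 0.0234; adjusted p = 0.266 with an estimated correlation). Pax6 rose by 0.97 (SE 0.0936, adjusted p = 7.2e-05), from 130 ± 1.86 CPM (SD, n = 2) to 254 ± 22.9 CPM (SD, n = 2), Zic4 by 0.74 (SE 0.0952) and Meis1 by 0.55 (SE 0.0740). Of 24 differentiation genes 9 rose, 3 fell and 12 did not pass (11 and 3 over the list alone), with a median of 0.32 (camera adjusted p = 0.000231, fry 0.0147; adjusted p = 0.169 with an estimated correlation). Gap43 rose by 1.31 (SE 0.124) and Dcx by 1.15 (SE 0.127), and Ncam1 fell by 0.89 (SE 0.106). The progenitor genes that rose numbered 4 without GFP control replicate 1, 5 without GFP control replicate 2 and 4 without Kif3a CRISPR replicate 1; the differentiation genes that rose numbered 6 without Kif3a CRISPR replicate 1. Of the differentiation genes 1 fell without GFP control replicate 2 or Kif3a CRISPR replicate 1. Of 17 stem cell and astrocyte markers 3 rose and 2 fell (3 and 2 over the list alone, camera adjusted p = 0.546, mean 0.02 against a median of -0.10). Sox2 and Sox9 fell by 0.79 (SE 0.0848) and 0.80 (SE 0.101). The number of these markers that rose was 1 without GFP control replicate 1 or 2 and 0 by edgeR without Kif3a CRISPR replicate 1.

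The hypoxia and glycolysis genes had the largest median change of the 23 lists tested in Kif3a CRISPR: 21 of 22 fell and 0 rose (21 and 0 over the list alone), with a median of -1.25 (camera adjusted p = 1.9e-53, fry 0.00536; adjusted p = 0.168 with an estimated correlation). Egln3 fell by 1.68 (SE 0.108, adjusted p = 8.4e-06), from 161 ± 5.82 CPM (SD, n = 2) to 50.4 ± 8.21 CPM (SD, n = 2). The glycolytic regulator Pfkfb3 fell by 1.49 (SE 0.0958), Slc2a3 by 1.11 (SE 0.0715) and the carbonic anhydrase Car9 by 3.12 (SE 0.401, adjusted p = 0.000366). Without GFP control replicate 1, which carried myeloid transcripts, 20 of these genes fell. Of 22 stress and unfolded protein response genes 15 fell, 0 rose and 7 did not pass (17 and 1 over the list alone), with a median of -0.87 (camera adjusted p = 1.9e-14, fry 0.0118; adjusted p = 0.169 with an estimated correlation). Atf5 fell by 3.06 (SE 0.304), Trib3 by 3.42 (SE 0.370) and Sesn2 by 1.70 (SE 0.148), while Hspa5, Calr and Pdia4 had log2 fold changes of 0.15, -0.03 and -0.03 and did not pass. The number of stress genes that fell was 13 without GFP control replicate 1 and 10 without Kif3a CRISPR replicate 1. Of 20 p53 targets 8 fell and 1 rose (9 and 1 over the list alone), with a median of -0.25 (camera adjusted p = 0.000389, fry 0.00536; adjusted p = 0.169 with an estimated correlation). Cdkn1a fell by 2.02 (SE 0.268) and Bbc3, a pro-apoptotic gene, by 0.98 (SE 0.137), while Mdm2 and Ccng1 did not pass (0.04 and 0.01). The p53 targets that fell numbered 5 without GFP control replicate 1, 5 without GFP control replicate 2 and 3 without Kif3a CRISPR replicate 1.

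**Figure D2:**
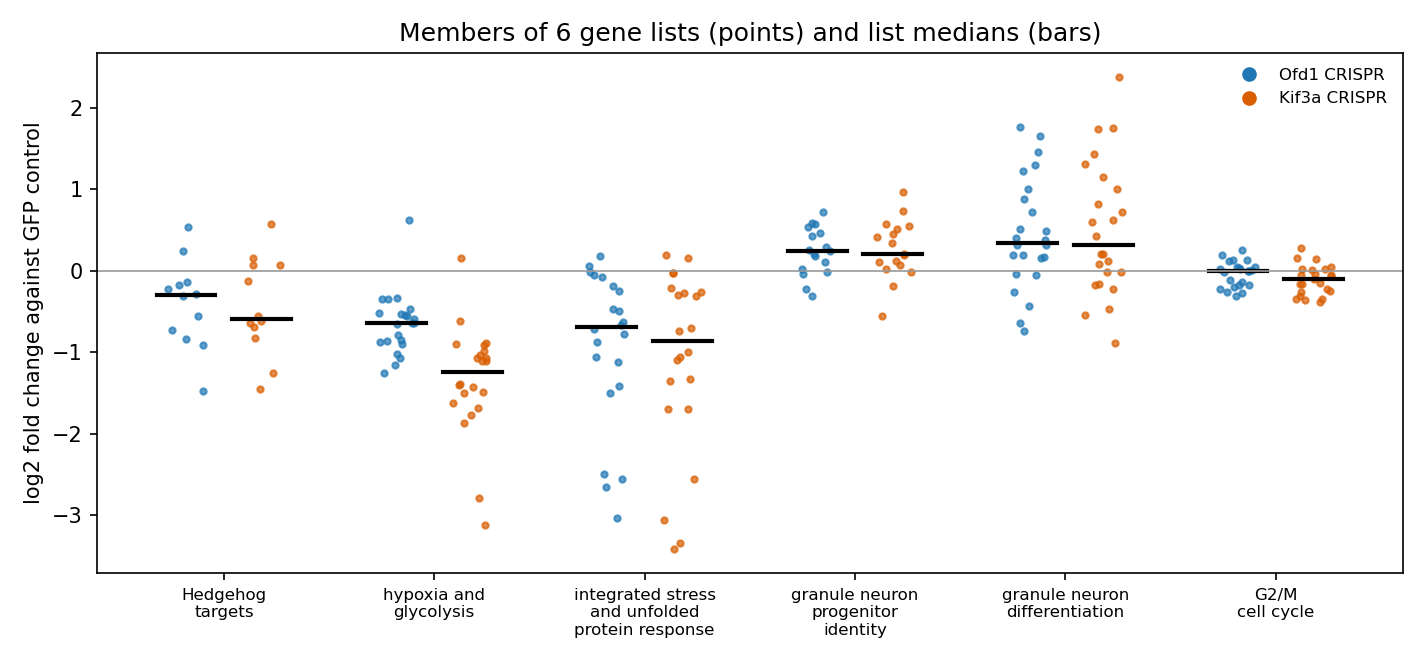
Log2 fold changes against GFP control of the tested members of 6 gene lists; each point is a gene, blue for Ofd1 CRISPR and orange for Kif3a CRISPR, and black bars are list medians. The hypoxia and glycolysis medians lie at -0.64 and -1.25, and the granule neuron differentiation medians at 0.35 and 0.32; the G2/M median in Ofd1 CRISPR, 0.00, flips sign with RLE factors.

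Of 24 G1/S genes 7 fell and 1 rose in Kif3a CRISPR (10 and 1 over the list alone, median -0.23, camera adjusted p = 0.000554), with Cdt1 down (-0.63, SE 0.0945). The list did not pass by fry (adjusted p = 0.130) or by camera with an estimated correlation (0.683). The number that fell was 3 without GFP control replicate 1, 2 without GFP control replicate 2 and 1 without Kif3a CRISPR replicate 1. Of 23 G2/M genes 5 fell and 1 rose (5 and 1 over the list alone, median -0.11, camera adjusted p = 0.110), and no member fell by edgeR without GFP control replicate 1, GFP control replicate 2 or Kif3a CRISPR replicate 1, and 2 fell without Kif3a CRISPR replicate 2. Of 18 ERK/MAPK feedback genes 7 fell (12 over the list alone, median -0.60, camera adjusted p = 2.5e-05; adjusted p = 0.169 with an estimated correlation). Dusp4 fell by 1.65 (SE 0.243) and Spred2, an inhibitor of ERK signalling, by 0.49 (SE 0.0728). That count was 3 without GFP control replicate 1, 2 without Kif3a CRISPR replicate 1 and 11 without Ofd1 CRISPR replicate 1. Of 23 interferon response genes 5 fell (5 lower and 1 higher over the list alone, median -0.33, camera adjusted p = 0.00548; adjusted p = 0.172 with an estimated correlation). Oasl2 fell by 1.23 (SE 0.139) and Rsad2 by 1.18 (SE 0.158), and 2 members fell without Kif3a CRISPR replicate 1. Of 12 Wnt targets 4 fell (4 over the list alone, median -0.38, camera adjusted p = 0.0136; adjusted p = 0.169 with an estimated correlation), with Wif1 down (-1.66, SE 0.219); 1 fell without GFP control replicate 2 and 1 without Kif3a CRISPR replicate 1. Of 14 Notch pathway genes 3 rose and 3 fell (3 and 3 over the list alone, camera adjusted p = 0.796), with Hey1 up by 1.505 (SE 0.196) and Notch3 down (-1.18, SE 0.129); 1 rose without GFP control replicate 1 or 2 or Kif3a CRISPR replicate 1 or 2. Of 11 BMP/TGF-beta targets 1 rose and 1 fell (0 and 1 over the list alone, 0.890, mean 0.09 against a median of -0.11); 0 fell by edgeR without GFP control replicate 2 or Kif3a CRISPR replicate 1 or 2, and 0 rose without these, GFP control replicate 1 or Ofd1 CRISPR replicate 2. Of 22 cholesterol genes 3 rose (2 over the list alone, median 0.11, camera adjusted p = 0.0476, fry 0.304, and camera 0.694 with an estimated correlation). The cholesterol call was lost without GFP control replicate 2 (0.153), Ofd1 CRISPR replicate 1 (0.0554) or 3 (0.0536), or Kif3a CRISPR replicate 2 (0.334). The number of cholesterol genes that rose was 0 without GFP control replicate 2, 1 without Kif3a CRISPR replicate 1 and 5 without Ofd1 CRISPR replicate 1, by edgeR.

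Of 29 kinesin-2 and intraflagellar transport genes 2 rose and 3 fell in Kif3a CRISPR, Kif3a among the latter (1 and 3 over the list alone, camera adjusted p = 0.583). Of 35 basal body, transition zone and BBSome genes 2 rose and 3 fell (2 and 3 over the list alone, 0.540). Kif3a itself was the 1 kinesin-2 and intraflagellar transport gene that fell without GFP control replicate 1 or without Kif3a CRISPR replicate 1 or 2, and 0 rose without Kif3a CRISPR replicate 1 by edgeR. Of the basal body genes 0 rose and 1 fell without GFP control replicate 1 or 2, 0 were called without Kif3a CRISPR replicate 1, 1 rose and 1 fell without Kif3a CRISPR replicate 2, and 5 fell without Ofd1 CRISPR replicate 1. Of 8 motile cilia markers 2 rose and 1 fell (3 and 1 over the list alone, 0.540); the median of -0.01 differs in sign from the mean, 0.41, and the test, and it flips with library totals alone (0.02). Foxj1 rose by 1.20 (SE 0.270, adjusted p = 0.00918; 0.119 without Kif3a CRISPR replicate 1). Of the motile cilia markers 1 rose without GFP control replicate 1 or 2 and 0 by edgeR without Kif3a CRISPR replicate 1. Of 5 oligodendrocyte lineage markers 3 fell (3 over the list alone, camera adjusted p = 0.110, fry 0.00536). The growth factor receptor Pdgfra fell by 1.26 (SE 0.260, adjusted p = 0.00605; 0.134 without Kif3a CRISPR replicate 1). Of the oligodendrocyte markers 1 fell without GFP control replicate 1 and 0 by edgeR without Kif3a CRISPR replicate 1. That list passed camera without Ofd1 CRISPR replicate 1 (adjusted p = 0.0460). Of 5 endothelial markers 3 fell (3 lower and 1 higher over the list alone, median -0.94, camera adjusted p = 0.0156; adjusted p = 0.197 with an estimated correlation), with Ramp2, a receptor partner of adrenomedullin, down (-1.51, SE 0.141); 1 fell without Kif3a CRISPR replicate 1. Of 10 fibroblast markers 4 fell (4 over the list alone, camera adjusted p = 0.0714, fry 0.0121). Fewer fell without GFP control replicate 1 or 2 or Kif3a CRISPR replicate 1. The fibroblast list passed camera without GFP control replicate 1 (adjusted p = 0.0244). Of 8 RNA quality signs 1 fell (1 over the list alone, 0.543), Neat1 (-0.58, adjusted p = 0.00315; 0.0715 without Kif3a CRISPR replicate 1).

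In all, 2584 genes changed in Kif3a CRISPR, 1183 higher and 1401 lower, of which 191 and 305 by more than 2-fold. The replicate block gave 3575 genes. Scaled by library totals alone, 2737 genes changed and 54.3% of them were higher, against 45.8% with TMM factors, so which direction held more genes depended on the scaling. By the criteria used for Ofd1 CRISPR, the largest rises were in Cmya5 (3.52), Igfbp5 (3.49, SE 0.325), Grik3 (3.47), Casz1 (3.33), the hyaluronan-degrading protein Cemip (3.07, SE 0.304), the intermediate filament Prph (3.00), Kcna1 (2.88), Mroh2a (2.58), B3galt2 (2.52) and Cdh23 (2.47). Apart from myeloid genes, the largest falls were in Trim66 (-3.91, SE 0.342), Mef2b (-3.73, SE 0.285), Trib3, Chac1 (-3.34), Car9 and Atf5. Calls were lost without Kif3a CRISPR replicate 1 for Cmya5 (adjusted p = 0.0634), Kcna1 (0.136) and Chac1 (0.104), and without GFP control replicate 2 for Kcna1 (0.0569). The total was 1100 genes without GFP control replicate 1, 1362 without GFP control replicate 2 and 686 without Kif3a CRISPR replicate 1.

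Both mutants were then set side by side. Of the changed genes, 1532 changed the same way in both, 684 higher and 848 lower, and 0 were called in opposite directions by edgeR. With the replicate block 2414 genes changed the same way. Among the largest shared rises whose calls held without any 1 library in both comparisons were Igfbp5, Grik3, Cemip, Prph, Mroh2a and Tspan4, and among such falls Trim66, Mef2b, Atf5 and Trib3. Among genes changed in both, 1223 had the larger change in Kif3a CRISPR, with a median ratio of the log2 fold changes of 1.16. Followed without each library in turn, these genes gave 905 (without Kif3a CRISPR replicate 1, median ratio 1.05) to 1388 (without Ofd1 CRISPR replicate 1, 1.34). Both comparisons share the 2 GFP control libraries. Independent lists of these sizes would share 80.3 genes upward and 113 downward, and 20 simulations of unchanged groups that share the controls gave 0.3 and 0.1 on average. The simulated comparisons called 1.9 and 2.05 genes on average, so their overlap shows how rarely unchanged groups give shared calls and is no benchmark for lists of 1915 and 2584 genes. Across the 12875 genes, which are not independent replicates, the log2 fold changes of both mutants had a Pearson correlation of 0.869 (0.541 in the simulations) and a Spearman correlation of 0.837 (0.508). Their covariance was 0.202 against a simulated 0.0199. With 2 control libraries the controls could not be split, so part of the excess may come from what these libraries share. Scaled by library totals alone, 1609 genes changed the same way and 55.6% of them were higher, against 44.6% with TMM factors. The number was 600 without GFP control replicate 1, 757 without GFP control replicate 2 and 591 without Kif3a CRISPR replicate 1.

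**Figure D3:**
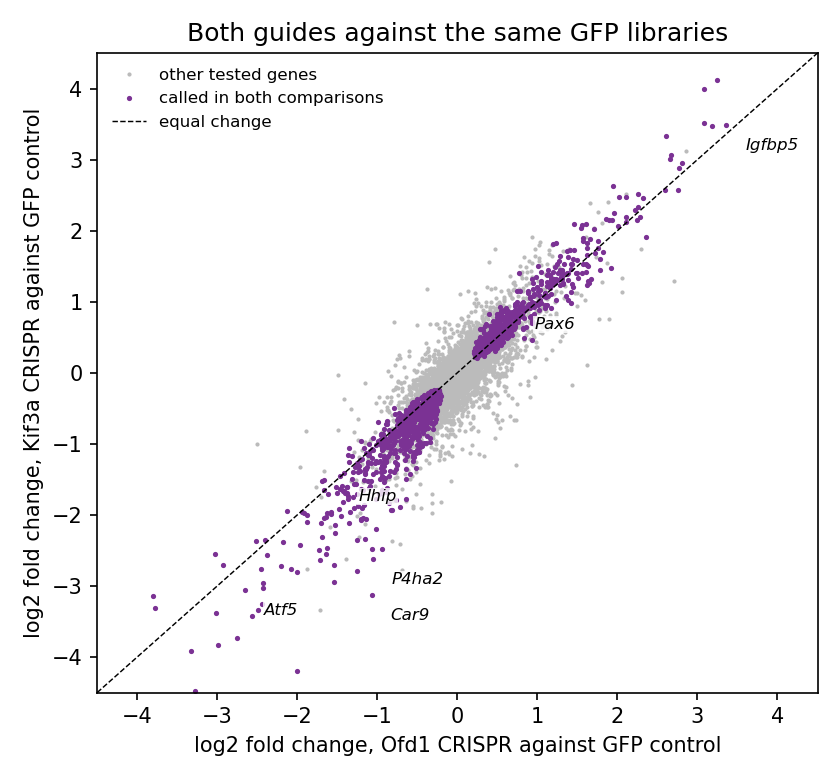
Log2 fold change against GFP control in Kif3a CRISPR (vertical axis) plotted against that in Ofd1 CRISPR (horizontal axis); each point is a tested gene, purple where it was called in both comparisons, and the dashed line marks equal change. The Pearson correlation across genes was 0.869, against 0.541 in simulated unchanged groups with shared controls; 17 genes lie outside the axes, which end at 4.5.

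The direct comparison of Ofd1 CRISPR with Kif3a CRISPR tests where the mutants differ. Genes of hypoxia and glycolysis were higher in Ofd1 CRISPR, that is, lower in Kif3a CRISPR. Of 22 such genes 8 were higher and 14 did not pass (20 higher over the list alone), with a median of 0.60 (camera adjusted p = 1.6e-62, fry 0.0743; adjusted p = 0.103 with an estimated correlation). Among them were Pfkfb3 (0.86, SE 0.0889, adjusted p = 0.00426), Egln3 (0.78, SE 0.101, adjusted p = 0.0058) and Slc2a3 (0.56, SE 0.0661, adjusted p = 0.00426). Of 12875 genes 23 differed, 22 higher and 1 lower. The number depended on the processing: 191 differed with the replicate block (124 higher and 67 lower), 86 with DESeq2 (82 and 4) and 80 without a filter on low counts (75 and 5), each time with the same 23 among them. The largest differences were in the incretin receptor Gipr (2.07, SE 0.333, adjusted p = 0.0338), the collagen prolyl hydroxylase P4ha2 (1.56, SE 0.189, adjusted p = 0.0046), the peptide hormone Apln (1.54, SE 0.181, adjusted p = 0.00426), the lysyl oxidase Loxl2 (1.41, SE 0.192, adjusted p = 0.00886) and Plekha2 (1.19, SE 0.151, adjusted p = 0.0058). The 1 lower gene was Ofd1 itself (-0.53, SE 0.0887, adjusted p = 0.0399). That difference came mainly from a higher level in Kif3a CRISPR (31.7 and 29.0 CPM). Ofd1 CRISPR (21.0, 20.03 and 22.0 CPM) lay near GFP control (22.6 and 23.2 CPM). Kif3a had a log2 fold change of 0.48 (SE 0.0859, adjusted p = 0.0588).

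The calls of the direct comparison were not kept without Kif3a CRISPR replicate 1, which leaves 1 library in that group, while the sizes of the differences were kept in part. Without that library 0 genes were called by edgeR, with 555 genes at an unadjusted p under 0.05, 16 genes called by DESeq2 and 0 by limma-voom, and 0 of the hypoxia genes were called. The log2 fold change without it was 1.52 for Gipr (adjusted p = 0.929), 1.21 for P4ha2 (0.257), 1.34 for Apln (0.265), 1.12 for Loxl2 (0.724), 1.05 for Plekha2 (0.265) and -0.47 for Ofd1 (0.924). It was 0.78 for Pfkfb3 (0.257), 0.62 for Egln3 (0.265) and 0.51 for Slc2a3 (0.257), and the hypoxia median was 0.47. The count was 50 without Ofd1 CRISPR replicate 1 and 12 without Kif3a CRISPR replicate 2, and the hypoxia count 15 and 5. Calls were also lost without Kif3a CRISPR replicate 2 for Gipr (0.0582), Loxl2 (0.0550) and Ofd1 (0.123), without Ofd1 CRISPR replicate 3 for Gipr (0.0829), and without Ofd1 CRISPR replicate 2 (0.128), GFP control replicate 1 (0.0946) or GFP control replicate 2 (0.0889) for Ofd1. No other list had a called member except basal body, transition zone and BBSome, which holds Ofd1. By camera the interferon (median 0.29, adjusted p = 3.7e-07), ERK/MAPK (0.16, 0.000468), Wnt (0.21, 0.0235) and G2/M (0.08, 0.0235) lists were higher in Ofd1 CRISPR. None of these calls held with an estimated correlation (adjusted p = 0.103, 0.309, 0.309 and 0.860) or by fry (0.0743, 0.218, 0.0944 and 0.714). The G2/M call was lost without Ofd1 CRISPR replicate 2 (0.343) or 3 (0.520) or Kif3a CRISPR replicate 1 (0.278), the Wnt call without Ofd1 CRISPR replicate 3 (0.183) or Kif3a CRISPR replicate 1 (0.200), and the ERK/MAPK call without Ofd1 CRISPR replicate 3 (0.0815). Other lists passed camera only when a library was left out. The stress list (0.15, adjusted p = 6.8e-06) and the G1/S list (0.11, 0.000599) were higher in Ofd1 CRISPR without Ofd1 CRISPR replicate 1, as they were without Kif3a CRISPR replicate 2 (0.00679 and 0.0122), and the progenitor identity list was lower without Ofd1 CRISPR replicate 1 (0.0386). The endothelial list was higher without GFP control replicate 1 (0.0452) or 2 (0.0384) or Kif3a CRISPR replicate 2 (0.0244), and the kinesin-2 and intraflagellar transport list without Kif3a CRISPR replicate 1 (0.0224). The cholesterol list was lower without Ofd1 CRISPR replicate 2 (0.0187) or Kif3a CRISPR replicate 1 (0.00175). The Hedgehog target list did not differ by the test (median -0.02, camera adjusted p = 0.819).

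Myeloid transcripts stood out in 1 control library. Chil3, a chitinase-like protein of macrophages, had 2635 counts in GFP control replicate 1 and 7 in GFP control replicate 2, with 62, 0 and 33 in the Ofd1 CRISPR libraries and 1 and 0 in the Kif3a CRISPR libraries. The chemokine Ccl22 had 1177 counts and 3 counts in the GFP control libraries, then 179, 1 and 13, then 0 and 0. Cd74 had 571 and 3, then 29, 1 and 10, then 0 and 0, and Ccl17 had 423 and 0, then 19, 0 and 13, then 0 and 0. Counts of Mmp12 were 351 and 1, then 10, 2 and 3, then 2 and 0, and those of Lgals3 337 and 14, then 21, 15 and 15, then 9 and 7. These genes were among the largest fitted falls, and no fold is given because the value rested on 1 library: without GFP control replicate 1 the adjusted p was 0.363 for Chil3 and 0.404 for Cd74 in Ofd1 CRISPR, and 0.457, 0.726, 0.425 and 0.398 for Chil3, Ccl22, Cd74 and Lgals3 in Kif3a CRISPR. Without Kif3a CRISPR replicate 1 or 2 the adjusted p in Kif3a CRISPR was 0.176 or 0.114 for Chil3, 0.237 or 0.164 for Ccl22, 0.185 or 0.116 for Cd74 and 0.170 or 0.107 for Lgals3. In Ofd1 CRISPR the Chil3 call was also lost without Ofd1 CRISPR replicate 2 (0.0602) or Kif3a CRISPR replicate 1 (0.0538) or 2 (0.0533), and the Cd74 call without Ofd1 CRISPR replicate 2 (0.104) or 3 (0.0801) or Kif3a CRISPR replicate 1 (0.0714) or 2 (0.0711). Of the macrophage list 3 of 14 genes were tested, which is too few for a list test; 0 fell in Ofd1 CRISPR by edgeR and 1, Ctss, in Kif3a CRISPR (2 and 1 over the list alone). The Ctss call was lost without Ofd1 CRISPR replicate 3 (0.0504) or Kif3a CRISPR replicate 1 (0.228) or 2 (0.154), and without GFP control replicate 2, 7 genes of this list fell in each mutant.

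**Figure D4:**
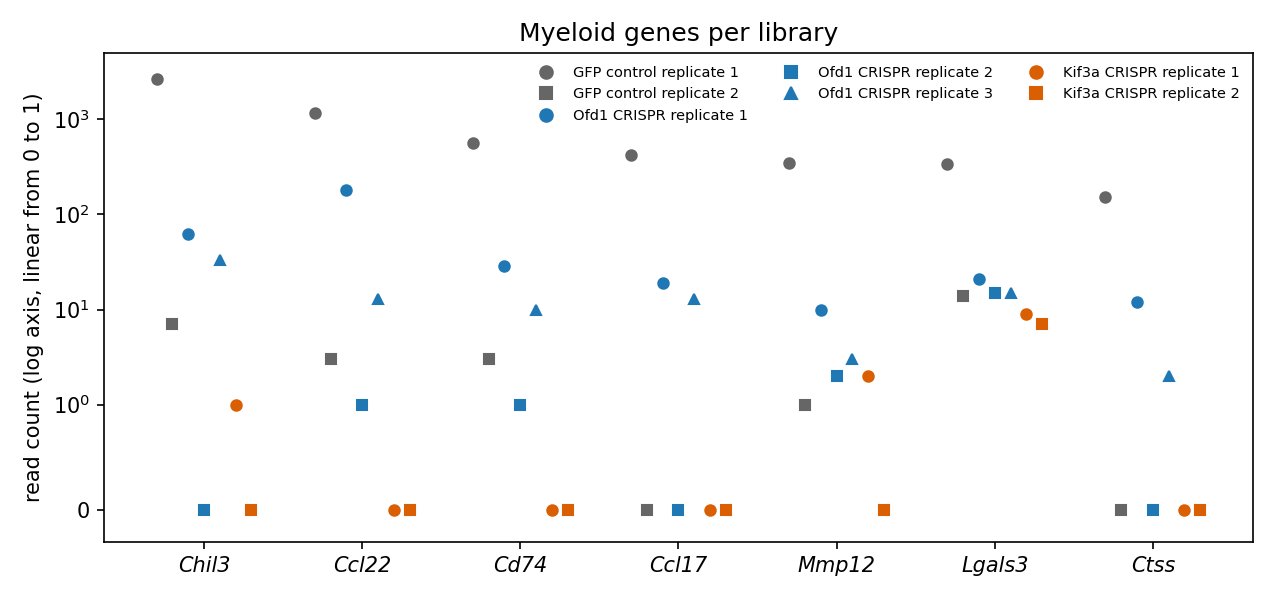
Read counts of 7 myeloid genes in each of the 7 libraries, on an axis that is logarithmic above 1 and linear from 0 to 1; colours mark the group and symbols the replicate. GFP control replicate 1 lies at 152 to 2635 counts for these genes and GFP control replicate 2 at 0 to 14.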

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

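The tests of macrophage transcripts, the hypoxia value without GFP control replicate 1, the test of GC content and length on the Hedgehog pattern in Kif3a CRISPR and the test of cycling cells were chosen only after the results were seen. The change against GFP differed between the mutants by the direct contrast in 23 genes, among them 8 members of the hypoxia and glycolysis list such as Pfkfb3, Egln3 and Slc2a3. All 8 were higher in Ofd1 CRISPR than in Kif3a CRISPR, and the hypoxia list did not pass with an estimated correlation (adjusted p = 0.103). Without Kif3a CRISPR replicate 1 the count over all genes was 0 by edgeR, with 555 genes at an unadjusted p under 0.05, 16 by DESeq2 and 0 by limma-voom, while the median of the hypoxia list was 0.47 against 0.60 with all libraries. It was 50 without Ofd1 CRISPR replicate 1 and 12 without Kif3a CRISPR replicate 2.

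GFP control replicate 1 held myeloid transcripts such as Ccl22 and Cd74: 51 genes had at least 50 counts there and at most 3 in GFP control replicate 2, with 6866 counts in all, or 0.0332% of that library, to which Chil3, with 2635 counts there and 7 in replicate 2, comes in addition. A response to the GFP guide is argued against, since the median ratio of replicate 2 to replicate 1 was 0 over the macrophage list members with at least 10 counts in replicate 1. Ofd1 CRISPR replicate 1 held 458 such counts. Spill of GFP control replicate 1 reads as their only source is argued against by unequal ratios. Ccl22 had 179 counts there against 1177 in GFP control replicate 1, and Cd74 had 29 against 571. A Monte Carlo chi-square over such genes gave p = 1e-05, the smallest that the draws made can give. The test asks for 1 ratio over all genes, so it cannot exclude spill beside another source. Ccl22 alone held 179 of the 458 counts. Myeloid cells or their RNA in GFP control replicate 1 stay a candidate source. Of the 14 macrophage list members 8 reached 10 counts in replicate 1, and 6 of these had at most 3 in replicate 2. Ctss with 152 and Lyz2 with 121 counts led them. The microglial genes C1qa, C1qb, C1qc, Trem2 and Cx3cr1 had 0, 4, 2, 1 and 0 counts in replicate 1. The number of 6 members lay between the bounds set for and against this source. Only 3 of the 14 genes were abundant enough over all libraries to be tested, and no sorting step is given in the sources used here.

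Hypoxia and glycolysis genes such as Egln3 and Slc2a3 were lower in both mutants, as were stress response genes such as Atf5 and Trib3; neither list passed with an estimated correlation (adjusted p = 0.208 and 0.168 for hypoxia, 0.208 and 0.169 for stress). Bias from GC content or transcript length is argued against for the hypoxia genes, since the median in Kif3a CRISPR was -1.23 after correction against -1.25 before, and -0.64 against -0.64 in Ofd1 CRISPR; the stress medians were -0.78 and -0.69 after correction. The library with myeloid RNA is argued against as the cause, since the hypoxia median in Kif3a CRISPR was -1.20 without GFP control replicate 1. Culture density or medium at harvest cannot be told apart from an effect of the guides, because cultures of a group may have shared both: the hypoxia score (mean log2 CPM) ranged by at most 0.315 within a group, while group means were 7.54 for GFP control, 6.89 for Ofd1 CRISPR and 6.27 for Kif3a CRISPR. A biological effect of targeting Ofd1 or Kif3a on these genes stays open and was not tested apart from culture.

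Hedgehog targets such as Ptch1 and Hhip were lower while granule lineage genes such as Pax6 were higher: 6 of 12 targets fell in each mutant, and 7 and 8 of 17 progenitor genes rose, while neither list passed with an estimated correlation (adjusted p = 0.212 and 0.197 for the targets, 0.312 and 0.266 for the progenitor genes). GC content or transcript length is argued against, since the difference between the medians of the granule progenitor and Hedgehog target lists was 0.54 after correction and 0.53 before in Ofd1 CRISPR, and 0.76 and 0.80 in Kif3a CRISPR (bootstrap interval of the change -0.05 to 0.07 and -0.10 to 0.10). The test for fewer cycling cells asked whether the G2/M genes fell by at least 0.5 of the Hedgehog change. No value here ties the sizes of these changes together, so the bound cannot decide the question. The G2/M median was 0.00105 in Ofd1 CRISPR (bootstrap interval -0.14 to 0.04, against a bound of -0.15) and -0.11 in Kif3a CRISPR (-0.23 to -0.04, against -0.29). These intervals draw genes as if independent, while the list's estimated inter-gene correlation was 0.498 and 0.499, so they are too narrow. The G1/S list was lower by camera in both mutants (adjusted p = 0.000235 and 0.000554). It did not pass with an estimated correlation (0.685 and 0.683) or by fry (0.168 and 0.130). Fewer cycling cells and a change within the cycle both stay open. The granule neuron differentiation list also had positive medians, 0.35 in Ofd1 CRISPR and 0.32 in Kif3a CRISPR. The progenitor medians were 0.24 and 0.21, so these lists give no direction for a shift along the lineage. Atoh1, which is a member of the Hedgehog target list, rose in both mutants. A lower Hedgehog output, with or without such a shift, is a hypothesis that these values leave open, and cilia were not analysed here.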

How the results depend on the processing

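The DESeq2 correlation between the mutants was chosen after seeing the data, as were the correlations with library totals alone, with only the 2 groups compared and with limma-voom, the DESeq2 and limma-voom counts without Kif3a CRISPR replicate 1, and the count of shared genes with the larger change in Kif3a CRISPR without each library. Over the alternatives, 57 of 75 values of gene counts and of the correlation were within the range taken as unchanged and 18 moved. A gene count was taken as unchanged up to a ratio of 1.5 either way, so that 3574 against 2584 genes was not counted as moved, and the correlation within its jackknife SE of 0.0701. For gene lists, 833 of 957 values kept their direction and their side of the threshold, 55 lost the call, 22 gained one and 47 that passed in neither case changed direction. For named genes, 2481 of 2788 kept both, 294 lost the call, 8 gained one and 5 reversed. The Ofd1 CRISPR, Kif3a CRISPR and shared counts were 1703, 2149 and 1346 with DESeq2, 1912, 2569 and 1527 with RLE factors, 1905, 2581 and 1522 with limma-voom, and 1706, 3574 and 1564 with only the 2 groups compared. DESeq2, limma-voom and the fits of only 2 groups were not used for list tests.

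DESeq2 was run on all genes with a count, and so also without the filter. It gave 86 genes in the direct contrast, among them all 23 found by edgeR, and a correlation of 0.768. Limma-voom on the filtered genes gave 21 genes and 0.877. The parts of tool and filter in the DESeq2 values were not separated. Without a filter on low counts the direct contrast gave 80 genes, with the same 23 among them, and the correlation was 0.726; genes near 0 counts enter these values. With an estimated correlation camera no longer passed for the Hedgehog target list in Ofd1 CRISPR or Kif3a CRISPR (adjusted p = 0.212 and 0.197). This setting leaves the medians of -0.29 and -0.59 as they are by construction. It also rests camera's test on the 4 residual degrees of freedom, and it ended all 26 list calls. Correlation among genes is thus not the whole cause. For p53 targets in Ofd1 CRISPR the estimate, 0.00901, lay below the preset 0.01, yet camera's unadjusted p rose from 7.6e-06 to 0.0107. With a replicate block, 3496 genes changed in Ofd1 CRISPR, 3575 in Kif3a CRISPR and 2414 the same way in both mutants. The direct contrast gave 191 genes (124 higher and 67 lower, against 22 and 1). Replicate 3 exists only in Ofd1 CRISPR, so the block fits that library exactly and takes it out of every contrast. Leaving that library out without a block gave 2831, 3041 and 1953 genes, and 31 in the direct contrast. The rest of the difference was not tested. The labels do not pair the samples by number, and the data could not settle it, so the libraries were taken to share only a number. Deviations from the group mean correlated at 0.199 and 0.190 between GFP control and Ofd1 CRISPR, -0.00857 between GFP control and Kif3a CRISPR, and 0.234 and 0.152 between Ofd1 CRISPR and Kif3a CRISPR libraries of the same number. In a group of 2 libraries the deviations are mirror images (correlation -1). Each Ofd1 CRISPR library therefore had to correlate better with 1 of the 2, and -0.00857 is the same value for both numbers. Little more than the signs is left to read. These went with the replicate number for Ofd1 CRISPR replicates 1 and 2, which is a weak hint from the data and not the design.

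Leaving out each of the 7 libraries in turn gave 664 to 2831 genes in Ofd1 CRISPR, 686 to 3119 in Kif3a CRISPR, 0 to 50 in the direct contrast by edgeR and 591 to 1953 the same way in both. The lowest counts came without GFP control replicate 1 (664) and without Kif3a CRISPR replicate 1 (686, 0 and 591), and the highest without Ofd1 CRISPR replicate 1 (3119 and 50) or Ofd1 CRISPR replicate 3 (2831 and 1953). The correlation ranged from 0.831 to 0.920 (jackknife SE 0.0701), and the Hedgehog target median from -0.34 to -0.27 in Ofd1 CRISPR and from -0.69 to -0.40 in Kif3a CRISPR. Of the named genes called in Ofd1 CRISPR 42 of 84 lost the call without some library, as did 49 of 91 in Kif3a CRISPR and 6 of 6 in the direct contrast. With 1 library left in a group, a lower count also reflects fewer samples.

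The 5 reversals were fitted values of myeloid genes without GFP control replicate 1, the library that held their counts. Over the omissions the log2 fold change in Ofd1 CRISPR ran from -6.30 to 2.19 for Chil3, from -5.56 to 2.14 for Cd74, from -5.22 to 6.47 for Ccl17 and from -4.22 to 0.33 for Lgals3. For Ccl17 in Kif3a CRISPR it ran from -11.7 to 0. The 0 arose where GFP control replicate 2 and both Kif3a CRISPR libraries, the libraries compared, stood at 0 counts. These fitted values depend on the prior count and none is a measured fold. A count of 3 in a library, 0.130 to 0.167 CPM, is the limit that depth sets on detecting a transcript.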

Other observations

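Genes of amino acid and one-carbon metabolism were looked at after Aldh1l2 and others of them had been seen to fall, so the values describe single genes and test no group. Cth, which makes cysteine, fell by 1.88 (SE 0.158) in Ofd1 CRISPR and by 2.00 (SE 0.181) in Kif3a CRISPR. The proline synthesis enzyme Pycr1 fell by 1.58 (SE 0.218) and by 1.96 (SE 0.252), and the mitochondrial folate enzymes Mthfd2 and Shmt2 fell by 1.47 (SE 0.199) and 0.94 (SE 0.110) in Ofd1 CRISPR. Cbs, which acts before Cth, did not pass (-1.02, SE 0.459, and -0.83, SE 0.492). It stood at 1.25 ± 0.86 CPM (SD, n = 2) in GFP control, below the 2 CPM asked of named genes. Its counts are too low to set it apart from Cth.

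The lists of ATF4-induced synthetases and of CREB targets were chosen after the comparisons with GFP control, before the values of their members were seen. A hypothesis is that lower activity of ATF4, the transcription factor of the integrated stress response, may underlie the lower stress response genes. It predicts that aminoacyl-tRNA synthetases induced by ATF4 fall more than the others. The 12 induced synthetases had a mean log2 fold change of -0.66 (SD 0.266) in Ofd1 CRISPR and the 7 others -0.04 (SD 0.201), a difference of -0.62 (exact two-sided permutation p = 0.000238 over 50388 arrangements of genes, which are not independent replicates). In Kif3a CRISPR the means were -0.73 (SD 0.284) and -0.07 (SD 0.214), a difference of -0.66 (exact permutation p = 0.000278). In each mutant 11 of the 12 induced synthetases fell, and in Kif3a CRISPR 6 fell without Kif3a CRISPR replicate 1. The induced synthetase that did not pass was Wars (0.11 in each mutant). Of the 7 others 1 fell and 1 rose in Ofd1 CRISPR, and 2 fell and 0 rose by edgeR in Kif3a CRISPR. Atf4 protein was not analysed here, and culture conditions stay open as a source of lower ATF4 activity.

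A further hypothesis is lower early gene output through cAMP and CREB, since Nr4a1 was among the largest falls. Of 17 listed CREB early targets 12 were tested; Nr4a1, Nr4a3 and Sik1, whose values had been seen, were left out of the list. In Ofd1 CRISPR 4 fell, such as the phosphodiesterase Pde4b by 0.94, and 2 rose, Arc (1.19) and Cited2 (0.60), with a median of -0.25 (camera p = 0.0489 for the single list, 0.152 with an estimated correlation). In Kif3a CRISPR 5 fell and 1, Cited2, rose, with a median of -0.42 (camera p = 0.00411, 0.0668 with an estimated correlation). In Ofd1 CRISPR 2 fell without GFP control replicate 1 or 2, and the Arc call was lost without GFP control replicate 1 (adjusted p = 0.0790). The direction in both mutants is the one that the hypothesis predicts, and the list test rests on the preset correlation. The ERK/MAPK feedback and early response list was also lower by camera (adjusted p = 0.00227 in Ofd1 CRISPR and 2.5e-05 in Kif3a CRISPR). That list did not pass with an estimated correlation (camera adjusted p = 0.312 and 0.169). Lower early gene output through CREB and through ERK was not told apart.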
